A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

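RNA was measured in 6 root tip libraries, 3 of wild type Zhonghua 11 and 3 of plt345, from seedlings grown on medium in a cycle of light and dark. Per the labels' protocols, total RNA was extracted with TRIzol and sequenced as paired ends on a BGISEQ-500. Whether the library kit marks strand and which genome build was used are not given in the sources used here. The submitters' processing notes name HISAT2, featureCounts 2.0.0 and DESeq2 1.38.3, with no parameters. Reads shared between near-identical genes and reads from antisense or overlapping genes therefore cannot be told apart here, and values of gene families are uncertain to that extent.

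The authors deposited 1 table of the whole series. Its 6 library columns hold size-factor-normalized counts, a signal that is never negative, and its mean column is the mean of these, per the file headers and the values. The table lists genes with at least 1 read in some library. Within a library, 100% of the deposited values were whole multiples of the value of 1 read, within 0.01 of a read, so whole reads were recovered. They summed to between 20759896 and 21309371 per library. The deposited table also gives the authors' log2 fold change of plt345 over wild type with its standard error, the Wald statistic as a score, and p-values with adjusted p-values, all from DESeq2 per the file headers. Of these the log2 fold change and adjusted p-value entered as an alternative, and 1789 genes with no adjusted p-value there were left without one.

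Genes with a mean of at least 10 normalized counts were tested on log2(value + 1) with limma 3.58.1 (lmFit, eBayes with trend, two-sided) in R 4.3.3, with no block and no covariate. The threshold was a Benjamini-Hochberg adjusted p under 0.05, and a second count took changes of at least 2-fold (absolute log2 fold change of at least 1). The pseudocount of 1 understates changes of low genes. Ratios of means are given on the linear scale. Where wild type had 1 to 3 reads the ratio of reads, scaled by depth, is given with its 95% exact binomial interval, and where it had none, a bound against 3 reads over the group. These intervals and floors cover counting error only. With edgeR the biological coefficient of variation was 2.70%, a low spread that lets small fold changes pass.

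Libraries of one genotype were compared before averaging. Within genotypes pairs differed by more than sampling noise, with a chi-square per gene of 1.44 to 2.12 against 53.2 to 54.6 between genotypes, so none was treated as a repeat of another. Replicate numbers were not taken as pairs. An exact permutation test of 3 libraries against 3 cannot go below p = 0.1.

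Gene names needed a separate step. The table names genes by locus identifiers of the form LOC_Os, and the reference table of gene symbols (assembly ASM3414082v1) does not hold such identifiers. Lists of genes had been fixed before the data were examined, with 272 pairs of symbol and locus identifier written from rice nomenclature. Each pair was checked against the reference table by asking whether a gene of the same symbol or synonym lies on the same chromosome within 1 Mb of the place interpolated from the other pairs. Of the pairs 214 matched, with a median distance of 0.025 Mb and a largest of 0.686 Mb, 55 symbols were not found, and 3 pairs were contradicted and left out. The interpolation was extended linearly beyond the first and last pair of a chromosome after CAB1R had fallen outside under another extension. This check shows that a pair is plausible, not that the identifiers are equal. The PLT symbols are not in the reference table, and their loci rest on nomenclature alone. Members whose symbol was not found stayed in the list tests, and an alternative leaves them out. Further lists defined by words in product names (such as histones, ribosomal proteins, expansins and peroxidases) were not analysed here, since no source used here gives product names.

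The 23 lists were tested with camera (preset correlation 0.01), beside camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over lists, and lists with fewer than 3 tested members were only counted. Genes named in the text follow a rule fixed before the data were examined. It takes PLT3 to PLT5, the 10 largest increases and 10 largest decreases among genes with a checked symbol, a mean of at least 50 and no overlap between genotypes, and up to 4 members with a checked symbol and the smallest adjusted p in each list. Not all of the last are printed. Names outside the rule are marked as chosen after their values were seen, and 4 loci without a name are given by identifier.

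The tests were tried on simulated data, with 50 genes changed at each of 4 fold sizes in counts drawn from these libraries' means and depths. Every gene was given the same spread, that of the edgeR coefficient of variation. Limma-trend recovered 60% at 1.25-fold, 86% at 1.5-fold, 92% at 2-fold and 96% at 4-fold, with 7 false calls among 23145 genes tested. Far more genes passed in the real data, so these rates describe the simulated setting only. The count of neighbouring genes used in the closing section exceeded random placement in 200 of 200 simulated sets with planted runs and in 0 of 200 without. In the former 60 runs of 4 neighbouring genes were planted, and calls were then dropped at random to keep their number. Weaker clustering was not tried.

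Alternatives fixed beforehand were DESeq2 1.42.0, edgeR with DESeq2 size factors, the authors' deposited table, no filter and a mean of at least 50, pseudocounts of 0.1 and 5, a replicate block, leaving out each library, an adjusted p of 0.01, a test against a change of at most 2-fold, and for lists an estimated correlation and ranks. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood, TMM) on the recovered reads, which called 16163 genes, scaling by library totals, and lists with only members found in the reference table. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.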

Results

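Gene expression was measured by RNA-seq in root tips of 7-day rice seedlings (Oryza sativa Japonica group), about 0.8 cm long, of the wild type cultivar Zhonghua 11 and of plt345, a line mutated in PLT3, PLT4 and PLT5. These are members of the PLETHORA (PLT) family of AP2-type transcription factors that act in root meristems. Each genotype had 3 libraries. The wild type libraries held 21309371, 21060393 and 21013147 reads counted on genes, and the plt345 libraries 20759896, 20762748 and 21035771. The table listed 31010 genes with a read in at least 1 library, of which 23166 had a mean of at least 10 normalized counts and were tested. Nothing in the labels says that the libraries came from separate batches of plants, so p-values measure the spread between these libraries, which may be technical. Values below are normalized counts, mean ± SD over 3 libraries per genotype, and log2 fold changes are plt345 over wild type on the log2(value + 1) scale, with the standard error of the limma fit.

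The transcripts of the PLT genes themselves were examined first. PLT3 (LOC_Os02g40070) was at 579.5 ± 5.92 in wild type and 576.4 ± 19.8 in plt345, a log2 fold change of -0.01 (SE 0.05, limma adjusted p = 0.897). PLT4 (LOC_Os04g42570) was slightly lower, at 269.8 ± 19.8 in wild type and 231.4 ± 13.0 in plt345 (log2 fold change -0.22, SE 0.08, limma adjusted p = 0.0198). PLT5 (LOC_Os01g67410) rose 2.39-fold, from 531.2 ± 28.9 to 1268 ± 9.02 (log2 fold change 1.26, SE 0.05, limma adjusted p = 1.1e-17). The call for PLT4 was lost in DESeq2 (adjusted p = 0.0989), with library totals as scaling (log2 fold change -0.13, adjusted p = 0.155), and without wild type replicate 1 (-0.17), wild type replicate 3 (-0.21) or plt345 replicate 2 (-0.18). The labels do not give the kind of mutation, and a mutated gene can keep its transcript, so these levels do not check the genotype.

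The comparison of plt345 with wild type asks which transcripts of the root tip depend on these PLT genes. Of the tested genes, 15751 passed the threshold, 7886 higher and 7865 lower in plt345 (limma-trend, Benjamini-Hochberg adjusted p under 0.05). The larger changes went mostly one way, with 3192 genes at least 2-fold higher and 687 at least 2-fold lower. The locus LOC_Os03g02470, to which the sources used here give no name, had no read in wild type and 2078 ± 27.3 normalized counts in plt345, at least 2035-fold higher against a floor of 3 reads over the wild type group. LOC_Os07g23660 had 1 read over the wild type libraries and 1847 ± 132 normalized counts in plt345, a ratio of 5429 with a 95% counting interval of 974 to 214470. In the other direction, LOC_Os10g18870 fell from 255.2 ± 16.0 to 0.654 ± 1.13, a ratio of 393 with a counting interval of 108 to 3254, and LOC_Os01g73700 fell 136-fold, from 1102 ± 29.6 to 8.09 ± 3.33. With library totals in place of the authors' size factors, a scaling chosen after seeing the data, 9362 genes were higher and 6014 lower, 60.9% higher against 50.1%.

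**Figure D1:**
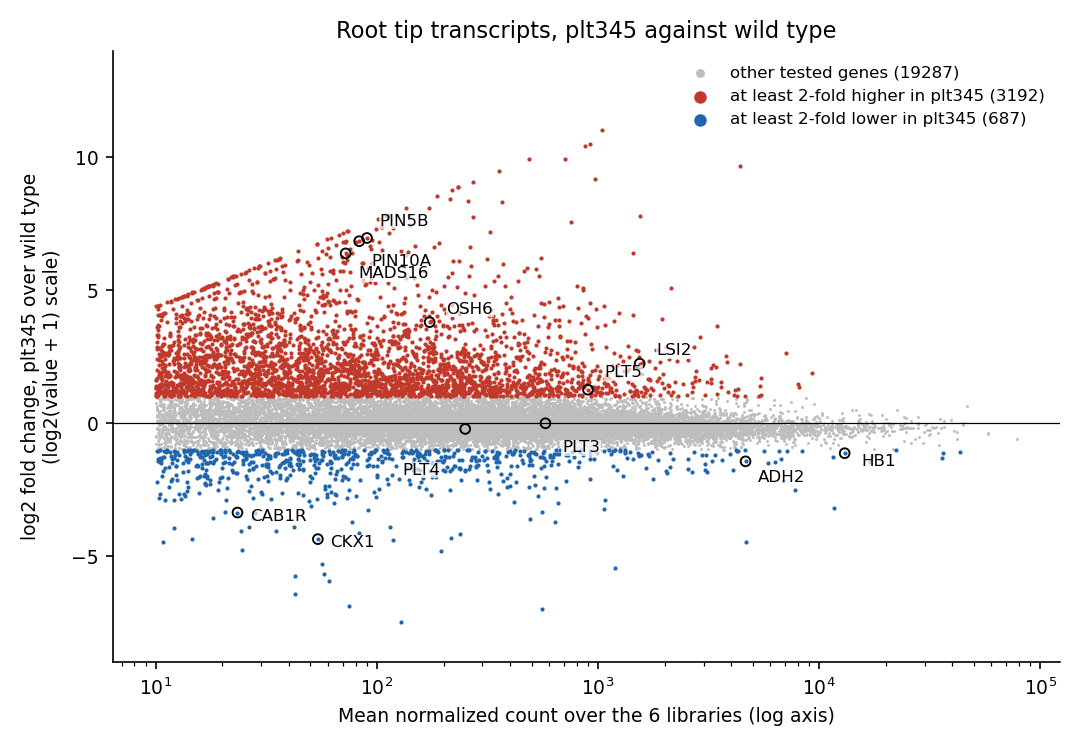
Mean normalized count over the 6 libraries (log axis) against the log2 fold change of plt345 over wild type for the 23166 genes tested. Red points are the 3192 genes at least 2-fold higher and blue points the 687 at least 2-fold lower in plt345 with an adjusted p under 0.05, grey points are all others, and circles mark named genes, among them PLT5 at 1.26 and CKX1 at -4.36.

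Among genes of the fixed lists with a checked symbol, a mean of at least 50 and no overlap between genotypes, the widest increases were those of PIN5B (LOC_Os08g41720) and PIN10A (LOC_Os01g45550), of the PIN family of auxin transport proteins. Each had 2 reads over the wild type libraries. The reference table crosses PIN5B with PIN5C, and the letters of PIN1A, PIN1B and PIN1C, as synonyms, so the locus and not the letter identifies these genes. PIN5B reached 179.5 ± 7.37 in plt345, a read ratio of 264 with a counting interval of 72.6 to 2182, and PIN10A reached 165.5 ± 19.9, a read ratio of 243 with an interval of 67.0 to 2013. MADS16 (LOC_Os06g49840), a B-class floral homeotic gene, had 4 reads over the wild type libraries and 440 over the plt345 libraries, 142.9 ± 15.5 normalized counts. OSH6, CKX11, OSH15, an AMT1 ammonium transporter gene, GH3.4, PIP1;3 and LSI2 followed, with rises from 14.4-fold to 4.72-fold. Under the same limits the widest decrease was that of CKX1 (LOC_Os01g09260), a cytokinin oxidase gene, which fell 24.6-fold from 103.8 ± 7.98 to 4.22 ± 1.51. ADH2, ADH1, HB1, PDC2, PIP1;1, MADS57, PIP2;5, PIN1A and TIP2;2 followed, between 2.71-fold and 1.76-fold lower. By the rule that chose them, each of these 20 genes passed adjusted p under 0.05 in limma-trend and no plt345 library overlapped a wild type library, which chance gives in 10% of genes with 3 libraries against 3. Some genes outside these limits, among them KSL7, CYP76M8 and CAB1R, changed more than the later of these 20 and are given with their lists.

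Of 23 gene lists fixed before the data were examined, 21 had at least 3 tested members. Camera with a preset correlation of 0.01 called 10 of them, 7 higher and 3 lower in plt345. With the correlation estimated from these libraries camera called 0 of 21, the lowest adjusted p being 0.168, and 6 lists had an unadjusted p under 0.05. The estimate lay below the preset 0.01 for the KNOX (-0.112), diterpenoid (-0.127), secondary wall (-0.282) and root meristem (-0.0715) lists. It lay above 0.01 for the other called lists. Correlation among members therefore does not account for the calls lost below it. The estimated version also rests on the few degrees of freedom that 6 libraries leave, so a lost call there can reflect low power. The fry test, which asks whether a list's own genes move one way on balance, called 18 of 21. It does not compare a list with the other genes, most of which also passed the threshold in these libraries. Its count therefore does not set the lists apart from other genes. Adjusted over the list alone, each list had as many members past the threshold as over all genes tested, except the auxin response factors, with 21 in place of 20. The member counts below stand beside those of all 23166 tested genes, of which 7886 were higher and 7865 lower. A list with members past the threshold in both directions is therefore not unusual here.

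The PLETHORA family list moved up in plt345. Of its 6 tested members, 4 were higher and PLT4 was lower, with a median log2 fold change of 0.78 (camera adjusted p = 0.0254, and adjusted p = 0.312 with an estimated correlation). The mutated genes PLT3, PLT4 and PLT5 are among these 6, and the list was not tested without them. Besides PLT5, PLT2 (LOC_Os06g44750) rose 9.75-fold, from 125.2 ± 19.4 to 1221 ± 16.4. PLT1 (LOC_Os04g55970) rose 1.72-fold from 1466 ± 18.5 to 2514 ± 63.5, and PLT6 (LOC_Os11g19060) rose 1.74-fold from 79.3 ± 6.92 to 138.2 ± 17.6. PLT1, PLT2 and PLT6 were named after their values were seen. Members of the family are similar in sequence, and reads shared between them could not be checked here. The call of the list was also lost with ranks in place of values (adjusted p = 0.0639).

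Regulators of the root meristem and of crown roots were also higher as a list. Of 7 tested members 6 rose and none fell, with a median log2 fold change of 0.75 (camera adjusted p = 0.0382, and adjusted p = 0.189 with an estimated correlation). QHB (LOC_Os01g63510), a homeobox gene expressed in the quiescent centre, rose 4.60-fold from 22.5 ± 4.60 to 103.3 ± 16.0, and WOX11 (LOC_Os07g48560), a crown root regulator, rose 11.7-fold from 3.06 ± 1.02 to 35.7 ± 7.90. These are also the 2 tested members of the WOX homeobox list. SHR2 (LOC_Os03g31880) rose 1.69-fold and SCR2 (LOC_Os12g02870) 1.22-fold, both GRAS-type regulators of ground tissue. SHR1 (LOC_Os07g39820), named after its value was seen, was at 283.5 ± 18.9 in wild type and 307.1 ± 14.2 in plt345, short of the threshold, which it passed with library totals (log2 fold change 0.20, adjusted p = 0.0194). The call of the list was lost among genes with a mean of at least 50 (adjusted p = 0.0709) and with only the members found in the reference table (adjusted p = 0.0731).

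The tested homeobox genes of the KNOX class, which act in shoot meristems, rose in root tips of plt345. All 3 tested members were higher, with a median log2 fold change of 2.47 (camera adjusted p = 0.0046, and adjusted p = 0.168 with an estimated correlation). OSH6 (LOC_Os01g19694) rose 14.4-fold from 22.5 ± 2.73 to 323.5 ± 11.1, OSH15 (LOC_Os07g03770) 5.62-fold from 44.9 ± 4.97 to 252.3 ± 17.6, and OSH71 (LOC_Os05g03884) 2.29-fold from 403.6 ± 17.3 to 924.1 ± 29.5. The other listed members were too low to test. OSH1 (LOC_Os03g51690) had 0 reads over the wild type libraries and 2 over the plt345 libraries, and OSH43 (LOC_Os03g56110) had 3 and 16. OSH1 and OSH43 were named after their values were seen. Among MADS-box genes, 7 of 15 tested members were higher and 5 lower, and the list did not pass (median log2 fold change 0.14, camera adjusted p = 0.45). MADS16 rose as given above, and MADS47 (LOC_Os03g08754), MADS26 (LOC_Os08g02070) and MADS56 (LOC_Os10g39130) rose 1.35-fold to 1.98-fold. MADS2 (LOC_Os01g66030) and MADS4 (LOC_Os05g34940), also B-class genes, did not pass. Their log2 fold changes were 0.14 and -0.19 (limma adjusted p = 0.627 and 0.492), and both were named after their values were seen. MADS57 (LOC_Os02g49840), MADS22, MADS27, MADS25 and MADS23 fell, by 2.00-fold for MADS57, the other 4 named after their values were seen. MADS23 lost its call in DESeq2 (adjusted p = 0.124), with library totals (log2 fold change -0.46), and without wild type replicate 2 (-0.49) or plt345 replicate 2 (-0.48). Of the 7 YABBY genes listed, which mark lateral organs of the shoot, none reached the mean of 10.

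The study's title names the Polycomb complex PRC2, which places the H3K27me3 mark, and the H3K4 demethylase JMJ703. As a list, genes of these regulators did not pass (7 tested, 1 higher and 3 lower, median log2 fold change -0.10, camera adjusted p = 0.537). JMJ703 (LOC_Os05g10770) was at 814.8 ± 28.0 in wild type and 826.8 ± 21.1 in plt345, a log2 fold change of 0.02 (SE 0.05, limma adjusted p = 0.701), and with library totals it was 0.11 (adjusted p = 0.0478). EZ1 (LOC_Os03g19480), a PRC2 methyltransferase gene, rose 1.42-fold from 374 ± 17.2 to 532.5 ± 17.72. CLF and EMF2B, entered as PRC2 genes under symbols that the reference table does not hold, fell 1.16-fold and 1.15-fold. JMJ705 (LOC_Os01g67970), an H3K27 demethylase gene, was 1.13-fold lower (log2 fold change -0.18). Its call was lost in DESeq2 (adjusted p = 0.151), with library totals (-0.09), and without wild type replicate 1 (-0.17), wild type replicate 2 (-0.16), plt345 replicate 2 (-0.18) or plt345 replicate 3 (-0.13). JMJ706 (LOC_Os10g42690), which acts on H3K9, and FIE2 (LOC_Os08g04270), a PRC2 subunit gene, had log2 fold changes of -0.10 and -0.06 and did not pass. JMJ703, CLF and EMF2B were named after their values were seen.

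Genes of the cell cycle and of DNA replication fell in plt345, by small amounts. Of 19 tested members 17 were lower, 1 was higher and 1 did not pass, with a median log2 fold change of -0.36 (camera adjusted p = 0.000303, and adjusted p = 0.168 with an estimated correlation). PCNA (LOC_Os02g56130), the sliding clamp of DNA polymerase, fell 1.32-fold from 2961 ± 46.0 to 2246 ± 51.4. MCM4 (LOC_Os01g36390), of the replicative helicase, fell 1.41-fold from 936.3 ± 54.7 to 665 ± 19.5. CYCB2;2 (LOC_Os06g51110), a mitotic cyclin, fell 1.48-fold from 1045 ± 50.7 to 708.4 ± 69.2, and CYCD4;1 (LOC_Os09g29100), a D-type cyclin, fell 1.46-fold from 811 ± 50.2 to 556.7 ± 33.3. The member that rose, named after its value was seen, was CYCD4;2 (LOC_Os08g37390), another D-type cyclin, from 432.5 ± 5.27 to 591.7 ± 61.1, and CYCA2;1 (LOC_Os12g31810), also named afterwards, was at 927.1 ± 29.3 and 881.1 ± 23.7. In the same libraries the secondary wall and nutrient uptake genes described next were higher, with median log2 fold changes of 0.82 and 1.63.

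**Figure D2:**
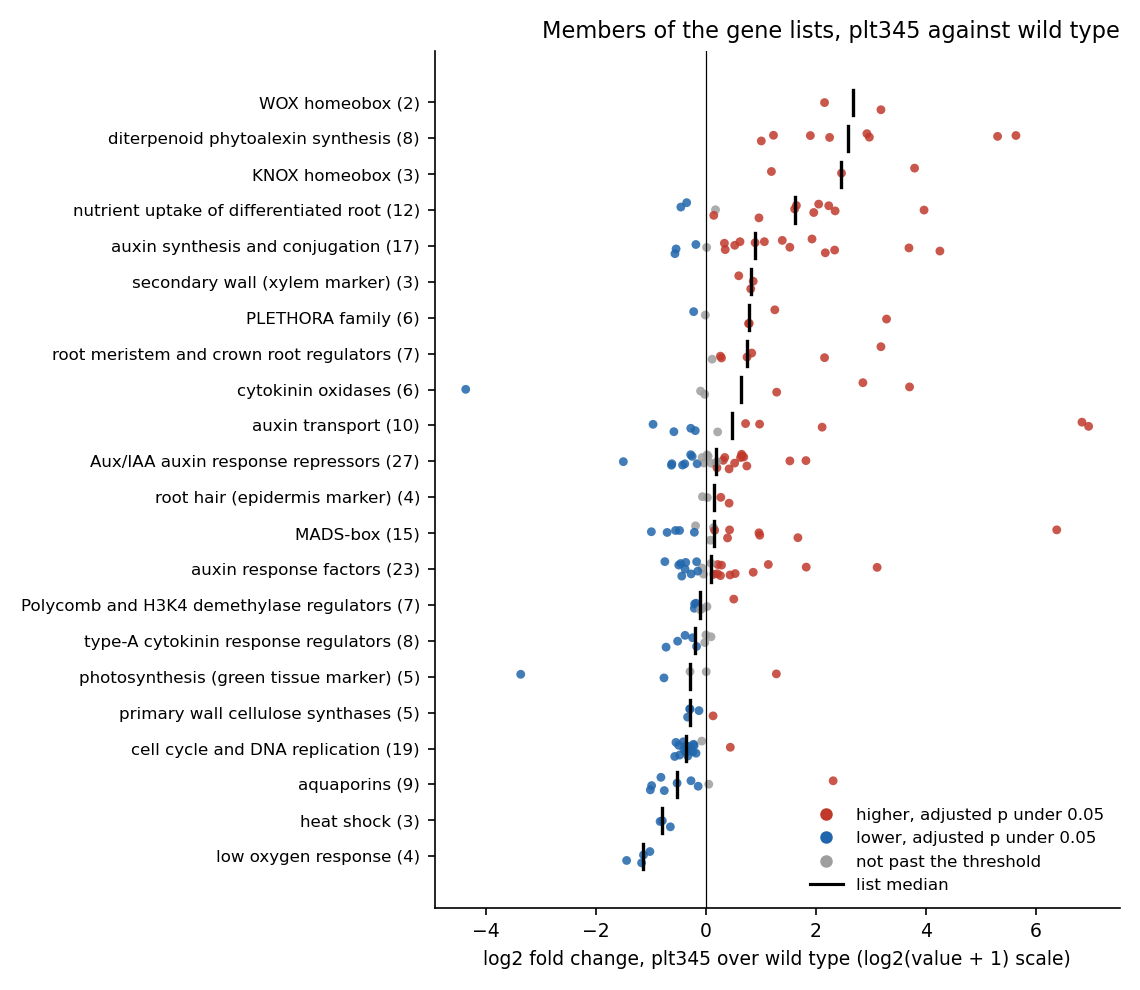
Log2 fold change of plt345 over wild type (log2(value + 1) scale) for each tested member of 22 gene lists, with the number tested in brackets and a black bar at the list median. Red and blue points passed adjusted p under 0.05 and grey points did not. The cell cycle list centres at -0.36 and the low oxygen list at -1.15, while the KNOX list centres at 2.47.

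All 3 cellulose synthase genes of secondary walls, which mark xylem, were higher, with a median log2 fold change of 0.82 (camera adjusted p = 0.00904, and adjusted p = 0.168 with an estimated correlation). CESA4 (LOC_Os01g54620) rose 1.82-fold from 935.6 ± 19.0 to 1702 ± 35.2, CESA9 (LOC_Os09g25490) 1.76-fold and CESA7 (LOC_Os10g32980) 1.52-fold. In the list of nutrient uptake genes of differentiated root, 9 of 12 tested members rose and 2 fell, with a median log2 fold change of 1.63 (camera adjusted p = 0.00246, and adjusted p = 0.168 with an estimated correlation). The silicon transporter genes LSI1 (LOC_Os02g51110) and LSI2 (LOC_Os03g01700) rose 3.90-fold from 1132 ± 10.0 to 4417 ± 128 and 4.72-fold from 539.7 ± 14.8 to 2545 ± 47.2. An AMT1 ammonium transporter gene (LOC_Os02g40730) rose 5.13-fold from 77.3 ± 10.4 to 396.6 ± 25.1, and NAR2.1 (LOC_Os02g38230), a partner of nitrate transporters, rose 3.15-fold. The 2 members that fell were CASP1 (LOC_Os04g58760), a Casparian strip gene of the endodermis, from 2159 ± 67.4 to 1577 ± 64.1, and the one entered as the metal transporter gene HMA3, by 1.27-fold. Both were named after their values were seen, and the symbol HMA3 is not in the reference table. The root hair list did not pass (2 of 4 higher, median log2 fold change 0.15, camera adjusted p = 0.505). Of its members, EXPA17 (LOC_Os06g01920), a root hair expansin gene, rose 1.34-fold, and CSLD1 (LOC_Os10g42750) was at 1403 ± 68.1 and 1431 ± 62.9, short of the threshold, which it passed with library totals (log2 fold change 0.12, adjusted p = 0.0201). Of the 5 cellulose synthase genes of primary walls 4 fell, with CESA8 (LOC_Os07g10770) 1.26-fold lower, from 16754 ± 218 to 13329 ± 190, and CESA3, named after its value was seen, rose 1.10-fold. That list did not pass (median log2 fold change -0.29, camera adjusted p = 0.0866), and CESA1, 1.09-fold lower, lost its call with library totals (log2 fold change -0.04).

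Auxin genes moved in both directions. In the auxin transport list 5 of 10 tested members were higher and 4 lower. The list had a median log2 fold change of 0.47, the same with PIN5B and PIN10A set at their lower bounds, and a mean of 1.58, and it did not pass camera (adjusted p = 0.884, direction up) or fry (adjusted p = 0.293, direction down). The abundant PIN1A (LOC_Os06g12610) fell 1.94-fold from 3852 ± 81.1 to 1982 ± 66.7, and PIN2 (LOC_Os06g44970), which carries auxin shootward in the outer root layers of other plants, fell 1.49-fold from 4755 ± 19.5 to 3182 ± 61.1. PIN1B and AUX1 fell 1.21-fold and 1.14-fold, and PIN1C, PIN1D and PIN9 rose by 1.65-fold to 4.77-fold. Genes of auxin synthesis and conjugation were higher in 13 of 17 tested members, with a median log2 fold change of 0.90 (camera adjusted p = 0.00904, adjusted p = 0.189 with an estimated correlation, and adjusted p = 0.0789 with only the members found in the reference table). GH3.4 (LOC_Os05g42150) rose 5.09-fold from 55.8 ± 11.3 to 283.9 ± 27.0, GH3.2 (LOC_Os01g55940) 2.87-fold and GH3.8 (LOC_Os07g40290) 1.87-fold, all of the GH3 family that joins auxin or jasmonate to amino acids. Of the 5 tested YUC genes of auxin synthesis 4 rose. YUC1 (LOC_Os01g45760) had 2 reads over the wild type libraries and 83 over the plt345 libraries, a read ratio of 39.6 with a counting interval of 10.6 to 332, YUC4 rose 3.96-fold from 19.7 ± 0.624 to 78.2 ± 5.59, YUC3 2.09-fold and YUC6 1.44-fold. GH3.11 (LOC_Os07g47490) fell 1.45-fold, YUC8 fell 1.47-fold and TAA1 fell 1.13-fold, the last losing its call with library totals (log2 fold change -0.09). The Aux/IAA repressors (12 of 27 higher, 8 lower, median log2 fold change 0.19) and the auxin response factors (11 of 23 higher, 9 lower, median 0.10) did not pass as lists, with camera adjusted p = 0.505 and 0.833. IAA13 (LOC_Os03g53150) fell 1.53-fold from 11668 ± 523 to 7607 ± 60.1, IAA21 (LOC_Os06g22870) rose 1.58-fold, ARF10 (LOC_Os04g43910) rose 3.55-fold from 214.4 ± 11.8 to 762 ± 18.7, and ARF12 (LOC_Os04g57610) fell 1.67-fold. PIN1B, PIN1C, PIN1D, PIN9, AUX1, the YUC genes and TAA1 were named after their values were seen, and the symbols PIN1D, AUX1, YUC3, YUC4, YUC6 and YUC8 are not in the reference table with a matching place.

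Among cytokinin genes, 3 of 6 tested cytokinin oxidases were higher and 1 lower (median log2 fold change 0.64, camera adjusted p = 0.505). CKX11 (LOC_Os08g35860) rose 7.40-fold from 40.8 ± 4.54 to 302 ± 33.7, CKX4 (LOC_Os01g71310) 12.7-fold from 4.75 ± 4.69 to 60.4 ± 5.48, and CKX5 (LOC_Os01g56810) 2.50-fold, against the fall of CKX1. Of 8 tested type-A response regulators, whose transcripts respond to cytokinin, 5 were lower and none higher (median log2 fold change -0.20, camera adjusted p = 0.147). RR4 (LOC_Os01g72330) fell 1.30-fold from 2029 ± 74.4 to 1562 ± 47.0, and RR3, a symbol outside the reference table that was named after its value was seen, fell 1.65-fold. RR10 (LOC_Os12g04500) was 1.18-fold lower, RR9 (LOC_Os11g04720) 1.12-fold and RR7 (LOC_Os07g26720) 1.44-fold. In DESeq2 the calls of RR9 (adjusted p = 0.068) and RR7 (adjusted p = 0.178) were lost, as they were with library totals (log2 fold changes -0.08 and -0.43). Without plt345 replicate 1 RR9 was at -0.13, short of the threshold. RR7 was short of it without wild type replicate 1 (-0.50), wild type replicate 3 (-0.44), plt345 replicate 2 (-0.43) or plt345 replicate 3 (-0.48), and with no filter on low values (adjusted p = 0.0562).

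Genes of diterpenoid phytoalexin synthesis, the antimicrobial compounds of rice that include momilactones, rose together. All 8 tested members were at least 2-fold higher, with a median log2 fold change of 2.59, the same with the members of 1 to 3 wild type reads at their lower bounds (camera adjusted p = 0.000638, and adjusted p = 0.168 with an estimated correlation). CYP99A3 (LOC_Os04g09920) rose 3.74-fold from 87.4 ± 13.4 to 326.8 ± 7.43, and CPS4 (LOC_Os04g09900) 2.35-fold from 148.1 ± 10.5 to 348.6 ± 16.3. KSL7 (LOC_Os02g36140) had 1 wild type read and 62.0 ± 2.32 normalized counts in plt345, a read ratio of 182 with a counting interval of 32.3 to 7230. CYP76M8 (LOC_Os02g36070) had 2 wild type reads and 56.7 ± 8.85 normalized counts, a read ratio of 83.4 with an interval of 22.8 to 694. By locus number every listed member lies near either LOC_Os04g09900 or LOC_Os02g36070. Genes placed so closely may not move independently, which the preset correlation of camera does not cover.

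Genes induced by low oxygen were lower in plt345. All 4 tested members fell at least 2-fold, with a median log2 fold change of -1.15 (camera adjusted p = 0.000303, and adjusted p = 0.168 with an estimated correlation). The alcohol dehydrogenase gene ADH2 (LOC_Os11g10510) fell 2.71-fold from 6786 ± 203 to 2502 ± 61.8 and ADH1 (LOC_Os11g10480) 2.24-fold from 1275 ± 64.2 to 568.8 ± 50.1. HB1 (LOC_Os03g13140), a non-symbiotic haemoglobin gene, fell 2.19-fold from 17909 ± 559 to 8171 ± 272, and PDC2 (LOC_Os03g18220), a pyruvate decarboxylase gene, fell 2.02-fold. Aquaporins were lower in 7 of 9 tested members, with a median log2 fold change of -0.52 (camera adjusted p = 0.00904, and adjusted p = 0.418 with an estimated correlation). PIP1;1 (LOC_Os02g44630) fell 2.01-fold from 29789 ± 1400 to 14803 ± 335, PIP2;1 (LOC_Os07g26690) 1.69-fold from 32690 ± 895 to 19379 ± 162, TIP2;2 (LOC_Os06g22960) 1.76-fold and PIP2;5 (LOC_Os07g26660) 1.98-fold. PIP1;3 (LOC_Os02g57720) went the other way, 4.97-fold higher from 570.6 ± 46.9 to 2838 ± 33.1, and PIP2;4, named after its value was seen, had a log2 fold change of 0.05, short of the threshold, and 0.14 with library totals, past it.

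**Figure D3:**
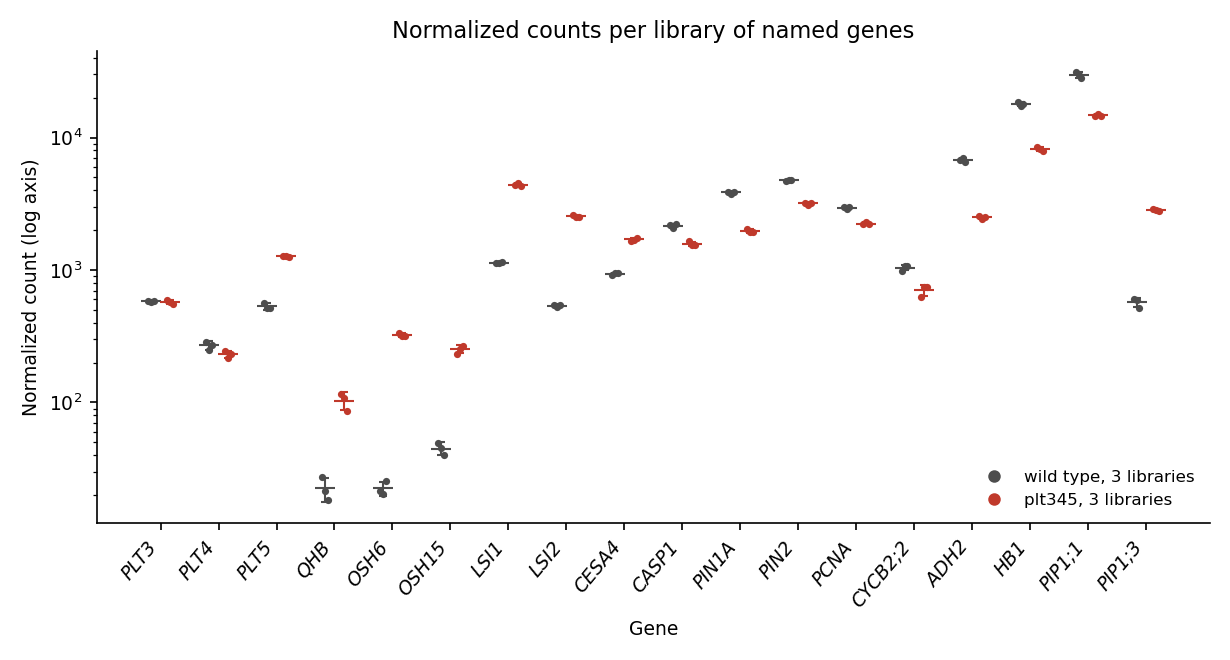
Normalized counts of 18 named genes (log axis) in each of the 3 wild type libraries (grey) and 3 plt345 libraries (red), with the mean and SD of each genotype as bars. PLT3 overlaps between genotypes, LSI2 lies at 539.7 and 2545 and ADH2 at 6786 and 2502.

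Of the remaining lists, the 3 tested heat shock genes were lower, with a median log2 fold change of -0.79, and the list did not pass (camera adjusted p = 0.164). They were HSP17.7 (LOC_Os03g16040), from 301.2 ± 8.37 to 193 ± 18.9, HSP17.9A (LOC_Os03g15960) and HSP101 (LOC_Os05g44340). Among markers of green tissue, 5 of 15 members reached the mean of 10, and the list did not pass (median log2 fold change -0.29, camera adjusted p = 0.505). CAB1R (LOC_Os09g17740), a chlorophyll-binding protein gene, fell 12.2-fold from 43.2 ± 3.107 to 3.56 ± 1.98. LHCB6 fell 1.74-fold and LHCB3 rose 2.58-fold, both named after their values were seen and outside the reference table, and LHCB6 lost its call without wild type replicate 2 (log2 fold change -0.61).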

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

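Scaling by library totals, edgeR on the recovered reads and lists limited to members found in the reference table were chosen after the data were seen. No gene called in the limma fit was called in the opposite direction in any of these fits. The count of genes past the threshold ran from 13358 with a mean of at least 50 to 17166 with no filter, the authors' deposited table giving 14494 and edgeR on the recovered reads 16163. The median log2 fold change of all tested genes was -0.01 with the authors' size factors and 0.08 with library totals, and small decreases such as those of CESA1 and TAA1 lost their call with the latter. The count at least 2-fold changed depended on the genes tested and on the null hypothesis. It was 2239 (1838 higher, 401 lower) with a mean of at least 50, 2581 (340 lower) in a test against a change of at most 2-fold, and with no filter 1070 genes were at least 2-fold lower. These follow from fewer genes, more genes or a stricter test. Leaving out each library in turn gave 14698 to 15346 genes, and 3780 to 3974 at least 2-fold changed.

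Replicate numbers did not pair the libraries, since same-numbered deviations correlated across genes at 0.024, 0.0193 and -0.000854. With the replicate number as a block 15913 genes passed, 3881 of them at least 2-fold changed, and 10 lists. Libraries 1 and 2 of plt345 correlated best with their own number and library 3 did not, and the correlations were too small to read as pairs.

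PLT4 kept its direction and lost its call at log2 fold changes of -0.22 in DESeq2 and in the authors' deposited table (adjusted p = 0.0989 and 0.0993) and -0.13 with library totals, and leaving out libraries gave -0.28 to -0.17. The cause was not tested. Camera with an estimated correlation called 0 lists in place of 10 (6 at an unadjusted p under 0.05). Among other named genes, apart from OSH1, OSH43, MADS2 and MADS4, 1695 comparisons with an alternative stayed the same, 27 lost the call and 5 gained it. Among lists 253 stayed the same, 14 lost the call and 1 gained it, the primary wall cellulose synthases with no filter (adjusted p = 0.0493). None reversed. The planned adjustment without independent filtering did not apply, as values per library were present. Depth limits what can be said of genes with few reads, such as those with 1 to 3 in wild type, whose ratios span more than 1 order of magnitude.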

Other observations

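The tests of library depth and of differentiated tissue, the counts of genes with at least 100 reads and the counts of genes in other groupings of the libraries were chosen after the results they measure had been seen. Detection differed between genotypes. Genes with at least 1 read numbered 27719 ± 55.4 (SD, n = 3) in wild type and 29010 ± 29.4 (SD, n = 3) in plt345, 1291 more, with no overlap between libraries (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). The plt345 library with the fewest reads (20759896) had 1259 more detected genes than the wild type library with the most (21309371), which argues against library depth as the source of the difference. Thinned to one number of reads, the libraries still differed by 1311 genes between genotypes, against at most 81 between libraries of one genotype. Thinning removed reads mostly from wild type and so could hardly narrow the difference, which means that it adds little to the comparison before it. At each level of expression more genes rose than fell by 2-fold. Among genes with a mean of 10 to 50 normalized counts, 31.4% were at least 2-fold higher in plt345 and 6.63% at least 2-fold lower. These shares were 14.5% and 2.70% at a mean of 50 to 500, and 4.08% and 1.43% over 500. The 50 most abundant genes took 8.58% to 8.86% of reads in wild type libraries and 7.58% to 7.68% in plt345 libraries.

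For this surplus of higher and newly detected genes, the tables argue against 2 explanations as its whole source and leave others open. A few genes taking most of the counts would shift genes of every level alike, and the median log2 fold change was 0.47 higher (0.472, bootstrap interval over genes 0.43 to 0.52) at a mean of 10 to 50 than over 500. Genomic DNA or another even background would spread over silent genes, yet of the reads that plt345 had on the 2784 genes with at most 1 wild type read, 84.2% (bootstrap interval over genes 77.9 to 88.1) lay on the 279 of them with the most reads, and the surplus remained among genes with at least 100 reads over a genotype (19196 in wild type, 20507 in plt345). The median of the 2784 genes was 3 plt345 reads, and their median gain was 0.973 normalized counts. A few strong rises can dominate the share of reads, so a low even background at the weakly detected genes is not excluded. A larger share of differentiated tissue in the plt345 root tips could not be decided. Of 19 tested markers 14 rose while 2 (CASP1 and the one entered as HMA3, a symbol the reference table does not hold) fell. Secondary wall genes (log2 fold changes 0.60 to 0.86) exceeded root hair genes (-0.06 to 0.42) by 0.67 in the median. The markers belong to different cell types, which need not rise alike, so unequal changes cannot exclude this explanation. The decreases of 17 of 19 cell cycle genes go with fewer dividing cells, and 4 of 5 primary wall genes also fell, in a list that did not pass. A change in some cell types, such as less meristem, more xylem or more of the cells that take up silicon, stays open. So does a loss of repression at silent genes, which may follow from the genotype but was not tested with chromatin data here.

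Genes higher in plt345 lay beside each other more often than chance placement gives, and so did the 687 genes at least 2-fold lower (69 pairs, against a mean of 20.3 and a highest of 36 in random placements), a pattern found in these data and tested on them. In the order of locus numbers, 715 pairs of neighbouring tested genes were both at least 2-fold higher, against a mean of 438 and a highest of 513 in 10000 random placements of the 3187 calls (one-sided permutation p = 0.0001, the smallest these can give). The level of expression accounted for little of it, since placing calls within 20 bins of mean expression gave a mean of 458.2 pairs and a highest of 533. A chromosome segment from another strain would gather the genes that are on in one genotype and nearly silent in the other, and of 96 such genes (at most 3 reads in one genotype and a mean of at least 50 in the other) the 5 fullest windows of 100 listed genes held 12.5%, against a mean of 11.7% for random genes. Of the 96, 92 were on only in plt345 and 4 only in wild type. These genes did not gather, but they are not the 3187 calls that form the pairs. A segment holding few such genes would be missed, so the test does not decide for the pairs. Reads shared between neighbouring copies of a gene, and neighbouring copies that respond alike, were not tested because no sequences were used here, and a shared chromatin state of neighbouring genes, in either direction of change, stays open as a hypothesis.

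The genotypes were also compared with other groupings of the same libraries. In the 10 splits of the 6 libraries into 3 and 3, only the real one (1 of 10) gave 15751 genes past the threshold and 3879 at least 2-fold changed. The highest of the others gave 0 and 0 (at most 66 genes at an unadjusted p under 0.05 in limma). Each of the others mixes both genotypes in each group. The genotype difference then widens the spread within groups, so few or no calls could result, and these counts do not measure what chance gives. For gene lists the real split (again 1 of 10) called 10 and the highest other 3. Camera with the preset correlation can thus call lists in a split where no gene passes, a limit that also holds for the 10. With 10 splits a share under 0.05 cannot be reached.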
